A study of Homo sapiens with 18 samples.

How the data were processed

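RNA was sequenced from 18 libraries of 3 cell lines of NK/T cell lymphoma, SNT-8, SNK-10 and SNT-16. Each line was given DMSO or icaritin for 12 h, with 3 replicates in each of the 6 groups; line, treatment, time and replicate number were read from the sample titles. Per the labels, total RNA was extracted with Trizol, 1 ug went into an MGIEasy library kit, and Bowtie2 and HISAT were used, with no versions or settings. The dose of icaritin, the genome build and the tool that made the gene values are not given in the sources used here. Nothing in the labels says whether the replicates were separate cultures.

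The deposited expected count of a gene is the estimated number of its fragments, not scaled to the library. Beside it the authors give FPKM, the fragments of a gene scaled by transcript length and by the fragments assigned to genes. The column headers name both units, and the values fit them: 60.3% to 61.6% of the expected counts of a library were whole numbers, within 0.005. Each library lists 16996 to 17461 genes, with a lowest FPKM of 0.01, so a gene missing from a file was taken as 0. The expected counts summed to between 9526431 and 10100453 per library, which bounds the precision for weakly expressed genes. Genes are keyed by NCBI Gene ID. Of 21662 IDs over all files, 21559 were given a symbol through the ID and 7 through a RefSeq transcript, from an annotation table of the GRCh38.p14 assembly; 96 had no match and kept their ID. That table was used only for names and neighbours, and no coordinates are given because the build of the deposited values is not stated.

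Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 14396 genes, and libraries were scaled by TMM. All 18 libraries entered a single quasi-likelihood fit (robust) with a mean for each of the 6 groups and 12 residual degrees of freedom. The common biological coefficient of variation was 4.4%. The contrasts were icaritin minus DMSO in each line, the mean of these 3 contrasts, an interaction test with 2 degrees of freedom, and the pairwise differences between lines. Tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over the 14396 genes of a contrast, with a threshold of 0.05. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD of 3 libraries. Fold changes are on the log2 scale. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic of its test. It is not reliable for genes almost without counts. The number of genes expected to change in the same direction in all 3 lines was computed from the sizes of the 3 lists as if these were independent.

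For gene groups, 35 lists were fixed before the data were examined, on the cell cycle, DNA damage and repair, stress responses, metabolism, cytokine signalling, cell death, the handling of the drugs of the GELOX regime (gemcitabine, oxaliplatin and asparaginase) and markers of cell types. The 32 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and adjustment over these lists. Camera with an estimated correlation and the rotation test fry stand beside it; fry tests whether the genes of a list move 1 way on balance and does not compare a list with other genes. For each list, the members that rose, fell or did not pass the threshold were counted with adjustment over all genes and adjusted over the list alone. The LXR targets, the AHR targets and the B and plasma cell markers had 4, 4 and 3 tested members, and only values of some members are given.

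The genes named in the text follow a rule fixed before the data were examined. PLK1 is always given. In each line, the rule takes the 8 largest rises and the 8 largest falls among genes past the threshold, with no overlap between the icaritin and DMSO libraries and at least 10 CPM on the mean of that line. For all lines, it takes the 10 largest average rises and the 10 largest falls among genes past the threshold in the same direction in each line; for the interaction, it takes the 8 smallest p-values; both need at least 10 CPM on the mean of all libraries. From each list described, it takes up to 4 members with the smallest p, and any member needed to say what a mixed list holds. Uncharacterised loci, antisense and other RNA-family names and sex-linked marker genes were left out of the rule, and some genes that it takes are not reported here.

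Replicates were compared for sampling noise by a chi-square per gene over genes with a mean count of at least 50; it lay between 1.36 and 8.11, above sampling noise in each pair of replicates. The replicate numbers did not pair DMSO with icaritin libraries, so no pairs entered the fit. The procedure was tested on simulated data made from these libraries, with 50 changed genes at each size of change. It recovered 68% to 78% of 1.5-fold changes and 98% to 100% of 4-fold changes in the 3 lines, with 4.5% to 5.6% of the calls false. It called a shifted list of 23 genes in each line and, in SNT-16, 1 other list. The simulated genes varied independently, and only 221 to 223 of 14396 were changed, far fewer than in the real data. The simulation therefore does not show how often lists of correlated genes are called falsely.

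The alternatives tried were the size factors of DESeq2 (RLE) and library totals in place of TMM, no count filter, a filter of at least 5 CPM, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) with a mean FPKM of at least 1, on log2(FPKM + 0.1) and without that filter, a replicate block, only the libraries of the line, adjusted p under 0.01, a log2 fold change of at least 1, camera with an estimated correlation, fry, and leaving out each library in turn. Counts without the SNT-8 or without the SNT-16 libraries were added after seeing the data. Other splits of the libraries into arms within each line were also fitted, all 10 in a line and 100 drawn over the 3 lines.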

Results

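RNA levels were measured in 18 libraries from the NK/T cell lymphoma lines SNT-8, SNK-10 and SNT-16, each treated for 12 h with DMSO, the solvent control, or with icaritin, a prenylated flavonoid of Epimedium plants. Each of the 6 groups held 3 libraries, and the expected counts of a library summed to between 9526431 and 10100453. Of the genes listed, 14396 had enough counts to be tested. The mitochondrial 16S ribosomal RNA gene RNR2 took a larger share of the counts after icaritin in each line. Its share went from between 1.19% and 1.33% to between 2.12% and 2.78% in SNT-8, from between 1.5% and 1.55% to between 4.59% and 5.12% in SNK-10, and from between 0.83% and 0.89% to between 1.65% and 1.77% in SNT-16. All p-values measure only the spread between these libraries, since nothing says that replicates were separate cultures.

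The control libraries of SNT-8 and SNT-16 resembled each other closely, and those of SNK-10 stood apart from both. Between DMSO libraries of SNT-8 and SNT-16, 148 genes (1% of those tested) differed at least 2-fold past the threshold. Against SNK-10, 2533 genes (17.6%) differed that much in SNT-8 and 2602 (18.1%) in SNT-16. Sex-linked marker genes were left out of the counts at 20 CPM that follow. Of 7549 genes with at least 20 CPM in the DMSO libraries of SNT-8, none lay below 33.75% of that level in SNT-16. In SNK-10, none lay below 4.7% of it, and 8 lay below 1 part in 8 of it. In the other direction, 185 of the 7699 genes with at least 20 CPM in SNK-10 lay below 1 part in 8 of that level in SNT-8. The first principal component held 76.6% of the variance and parted SNK-10 from both SNT lines, the second held 15.8% and parted icaritin from DMSO, and the third held 2.4% and parted SNT-8 from SNT-16. Across genes, Pearson's r on the log2 CPM was 0.988 to 0.992 between replicates, 0.973 to 0.982 between the arms of a line, and 0.879 to 0.989 between DMSO libraries of different lines; genes are not independent replicates.

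**Figure D1:**
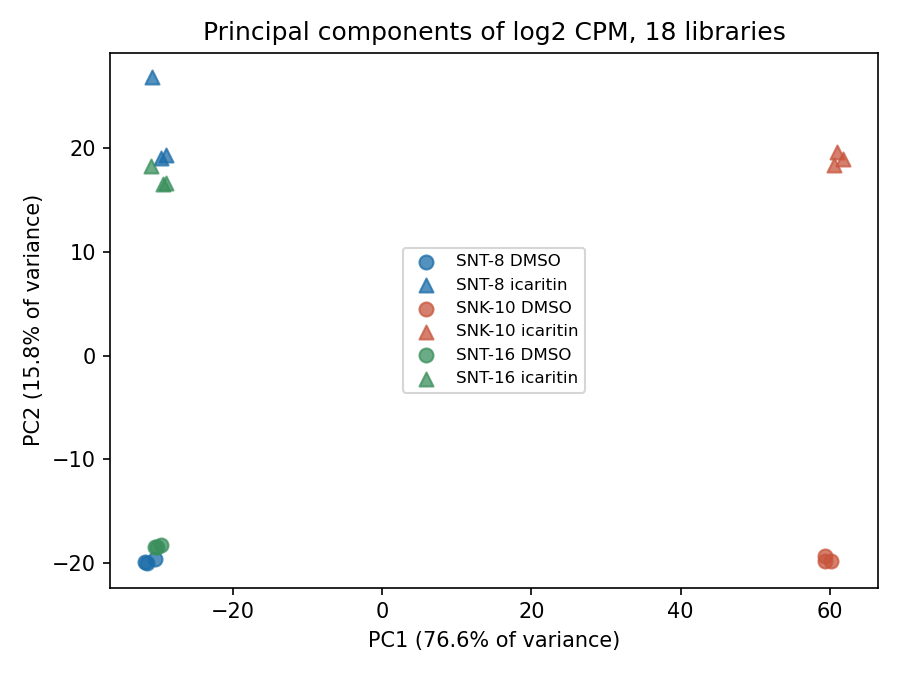
Scores of the 18 libraries on the first and second principal components of log2 CPM, with 1 point per library. Component 1 (76.6% of the variance) sets SNK-10 apart from SNT-8 and SNT-16, and component 2 (15.8%) sets icaritin apart from DMSO libraries.

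The title of the series names PLK1, the mitotic polo-like kinase, as the target of icaritin, and the RNA of PLK1 (NCBI Gene 5347) was lower after icaritin in all 3 lines. In SNT-8 it went from 245 ± 8.01 CPM to 71.3 ± 25.3 CPM (SD, n = 3 each), a log2 fold change of -1.78 (SE 0.177, adjusted p = 1.83e-06). In SNK-10 it went from 256 ± 16.2 to 109 ± 4.60 CPM, with -1.23 (SE 0.170, adjusted p = 4.54e-05). In SNT-16 it went from 250.2 ± 7.58 to 74.7 ± 7.77 CPM, with -1.74 (SE 0.176, adjusted p = 2.65e-06). The average log2 fold change was -1.58 (SE 0.101, adjusted p = 8.00e-09), and the test that the fall differed between lines did not pass the threshold (adjusted p = 0.238). All 9 icaritin libraries lay between 42.4 and 112.1 CPM and all 9 DMSO libraries between 236 and 271.9 CPM. In SNT-8, icaritin replicate 2 held 42.4 CPM and the other icaritin replicates 82.4 and 89.2 CPM. In the annotation PLK1 overlaps another tested gene, which had a mean of 2.107 CPM against 167.8 CPM for PLK1. These values are of RNA; the protein and its kinase activity were not analysed here.

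**Figure D2:**
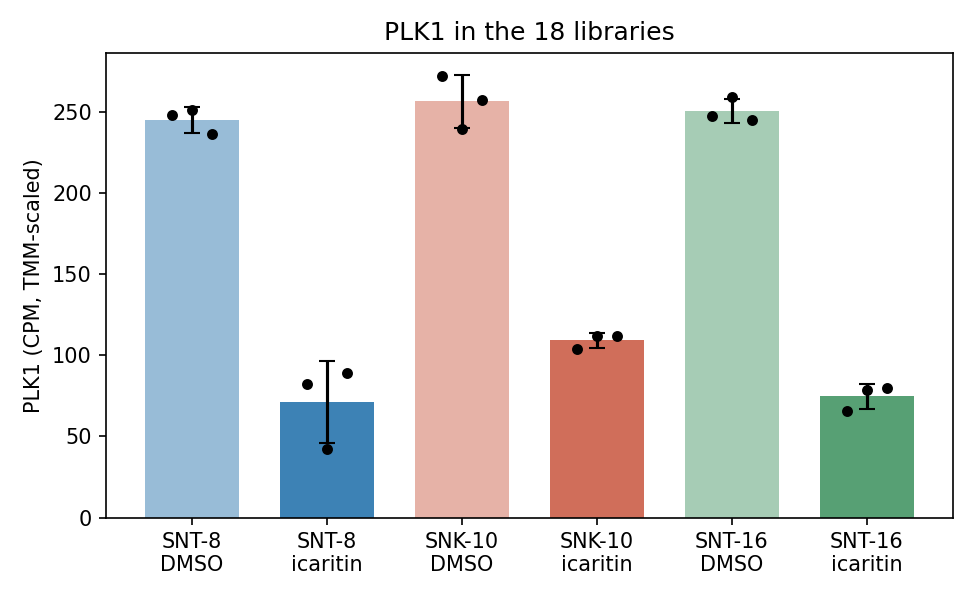
PLK1 RNA in CPM in each of the 18 libraries by line and treatment, with points for libraries and bars for the mean and SD of 3. All icaritin libraries (42.4 to 112.1 CPM) sit below all DMSO libraries (236 to 271.9 CPM).

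In SNT-8 cells, icaritin raised RGS1, a brake on G protein signalling in lymphocytes, from 5.35 ± 0.716 to 42.8 ± 4.86 CPM (SD, n = 3 each), with a log2 fold change of 3.00 (SE 0.149, adjusted p = 9.22e-14). It lowered CXCR3, a chemokine receptor of activated lymphocytes, with a log2 fold change of -2.88 (SE 0.133, adjusted p = 7.11e-12), and the chemokine gene CCL2, with -2.41 (SE 0.0790, adjusted p = 2.62e-21). Most genes of the ATF4 and integrated stress response list rose, and most genes of the ribosome biogenesis, heat shock and cholesterol synthesis lists fell. The largest rises also took in KLHDC7B (3.11), TNFSF4, which encodes the OX40 ligand (2.74), the cyclin G2 gene CCNG2 (2.65), the mitophagy receptor gene BNIP3L (2.50), the adhesion gene NECTIN4 (2.44), KLHL24 (2.34) and the T cell inhibitory receptor gene CTLA4 (2.31), with log2 fold changes in brackets. The largest falls also took in TSPOAP1 (-3.01), TANC2 (-2.58), HPDL (-2.56), the mitotic cyclin gene CCNB1 (-2.20), the zinc transporter gene SLC39A10 (-2.19) and BRINP2 (-2.01). The naming rule took only genes with all 3 icaritin libraries on the same side of all 3 DMSO libraries. In all, 7062 genes (49.1% of those tested) passed the threshold, 3460 higher and 3602 lower after icaritin, with a median absolute log2 fold change of 0.44. At least 2-fold changes were seen for 743, 414 of them upwards.

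Among the lists in SNT-8, the ATF4 and integrated stress response genes rose: of 37 tested, 33 rose, 0 fell and 4 did not pass (33 and 0 adjusted over the list alone). SESN2 was at 1.92, CTH at 1.93, DDIT3 at 2.08 and TRIB3 at 1.80. Of 39 MYC and ribosome biogenesis genes, 0 rose, 38 fell and 1 did not pass (0 and 38 adjusted over the list alone). NOP16 was at -1.62, WDR3 at -1.35, NOP56 at -1.01 and MYC itself, chosen after its value was seen, at -1.28. Of 19 heat shock genes, 0 rose, 15 fell and 4 did not pass (0 and 15 adjusted over the list alone). HSPA8 was at -1.21, STIP1 at -1.08 and HSP90AB1 at -0.77. Of 24 genes of cholesterol synthesis and SREBP2, 2 rose, 19 fell and 3 did not pass (2 and 19 adjusted over the list alone). LSS was at -1.24, DHCR7 at -1.08 and FDPS at -0.70 among the falls and CYP51A1 at 0.70 and STARD4 at 0.34 as the rises. Of 35 genes of homologous recombination and the Fanconi anaemia pathway, 23 rose, 5 fell and 7 did not pass (24 and 5 adjusted over the list alone). PALB2 was at 0.78 and BARD1 at 0.62, against MUS81 at -0.29 and FANCL at -0.34. Of 30 lysosome and autophagy genes, 19 rose, 1 fell and 10 did not pass (19 and 2 adjusted over the list alone). WIPI1 was at 1.08 and MAP1LC3B at 0.99. Of 13 BCL2 family genes, 7 rose, 2 fell and 4 did not pass (8 and 2 adjusted over the list alone). Those that rose included the death-promoting BBC3 (1.80) and BCL2L11 (0.96) and the survival genes BCL2 (0.93) and MCL1 (0.27). Those that fell were BCL2A1 (-1.66), a survival gene, and BID (-1.42), a death-promoting gene whose adjusted p was 0.0593 without SNT-8 icaritin replicate 2. These 7 lists passed the threshold with the preset correlation (adjusted p between 4.86e-25 and 0.00629) and with an estimated correlation (between 0.00175 and 0.0320).

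A further 8 lists in SNT-8 passed with the preset correlation and lost the call with an estimated correlation. Of 40 genes of G2/M and mitosis, 0 rose, 37 fell and 3 did not pass (0 and 37 adjusted over the list alone). KIF20A was at -1.88, CDC20 at -1.76, PTTG1 at -0.81 and NUF2 at -0.83 (adjusted p = 1.14e-15, and adjusted p = 0.152 with an estimated correlation). Of 29 p53 targets, 25 rose, 0 fell and 4 did not pass (25 and 0 adjusted over the list alone). MDM2 was at 1.21, BBC3 at 1.80, BTG2 at 0.96 and POLH at 0.77 (adjusted p = 0.0723 with an estimated correlation). Of 31 hypoxia and glycolysis genes, 21 rose, 0 fell and 10 did not pass (21 and 1 adjusted over the list alone) (adjusted p = 0.221 with an estimated correlation). Of 12 FOXO targets, 7 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone) (adjusted p = 0.0939 with an estimated correlation). Of 40 interferon-stimulated genes, 4 rose, 21 fell and 15 did not pass (5 and 21 adjusted over the list alone) (adjusted p = 0.221 with an estimated correlation). Of 45 genes of G1/S and DNA replication, 22 rose, 8 fell and 15 did not pass (22 and 8 adjusted over the list alone) (adjusted p = 0.516 with an estimated correlation). Of 41 cytosolic ribosomal protein genes, 9 rose, 0 fell and 32 did not pass (9 and 0 adjusted over the list alone) (adjusted p = 0.615 with an estimated correlation; with the preset correlation, adjusted p = 0.114 without SNT-8 icaritin replicate 2), and of 10 MHC class II genes, 0 rose, 6 fell and 4 did not pass (0 and 7 adjusted over the list alone) (adjusted p = 0.388 with an estimated correlation). The DNA damage signalling list did not pass (adjusted p = 0.908). Of its 27 genes, 8 rose, 7 fell and 12 did not pass (8 and 8 adjusted over the list alone). The checkpoint kinase gene ATR was at -0.59, its partner ATRIP at -0.76, TIMELESS at 0.40 and H2AX, chosen here and in the other lines after its values were seen, at -1.22. TSPOAP1, TNFSF4 and KIF20A overlap other tested genes in the annotation, so the split of reads between them is uncertain.

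In SNK-10 cells, the largest rise was in CCNG2, from 8.39 ± 0.940 to 89.0 ± 7.34 CPM (SD, n = 3 each), a log2 fold change of 3.40 (SE 0.111, adjusted p = 4.87e-22). CTH, which encodes the cysteine-forming enzyme cystathionine gamma-lyase, rose with 2.84 (SE 0.0780, adjusted p = 3.70e-27), and KLHL24 rose with 2.72 (SE 0.134, adjusted p = 1.59e-19). MAT2A, which encodes the enzyme that makes S-adenosylmethionine, fell with -1.76 (SE 0.0490, adjusted p = 3.70e-27), and RRS1, a ribosome biogenesis gene, fell with -1.77 (SE 0.0860, adjusted p = 3.87e-19). The stress response, ribosome biogenesis, chaperone, lysosome and BCL2 family lists moved in the directions seen in SNT-8. The other large rises were in ARRDC3 (2.66), CREBRF (2.49), TP53INP1 (2.44), the retinaldehyde reductase gene DHRS3 (2.33) and the signalling adaptor gene GAB2 (2.32). The other large falls were in TSPOAP1 (-3.02), HPDL (-2.30), SLC39A10 (-2.05), the noncoding RNA gene DANCR (-1.88), DEPP1 (-1.87) and the ribosome biogenesis gene PPAN (-1.78). The naming rule took only genes with all 3 icaritin libraries on the same side of all 3 DMSO libraries. In all, 6970 genes (48.4%) passed the threshold, 3511 higher and 3459 lower, and 709 changed at least 2-fold, 353 of them upwards.

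Of 37 ATF4 and integrated stress response genes in SNK-10, 32 rose, 1 fell and 4 did not pass (32 and 1 adjusted over the list alone). SLC3A2 was at 1.42, PSAT1 at 1.54 and AARS1 at 1.01. Of 39 MYC and ribosome biogenesis genes, 0 rose, 38 fell and 1 did not pass (0 and 38 adjusted over the list alone). NOP56 was at -1.27, WDR3 at -1.35 and NOP16 at -1.46. Of 19 heat shock genes, 0 rose, 16 fell and 3 did not pass (0 and 16 adjusted over the list alone). HSPA8 was at -1.30, STIP1 at -1.03 and FKBP4 at -0.83. Of 30 lysosome and autophagy genes, 23 rose, 0 fell and 7 did not pass (24 and 1 adjusted over the list alone). LAMP1 was at 0.59 and CTSD at 0.62. Of 13 BCL2 family genes, 9 rose, 0 fell and 4 did not pass (9 and 0 adjusted over the list alone). BBC3 was at 1.93, BCL2L11 at 1.38, BCL2 at 0.82 and MCL1 at 0.34. Of 12 FOXO targets, 9 rose, 0 fell and 3 did not pass (9 and 0 adjusted over the list alone). TXNIP was at 1.51, CDKN1B at 0.85 and SESN1 at 1.86. Of 35 genes of homologous recombination and the Fanconi anaemia pathway, 20 rose, 6 fell and 9 did not pass (21 and 6 adjusted over the list alone). RAD54L was at 0.77, PALB2 at 0.79 and BARD1 at 0.68 against FANCL at -0.74 and RAD51C at -0.41. Of 24 genes of cholesterol synthesis and SREBP2, 4 rose, 16 fell and 4 did not pass (4 and 16 adjusted over the list alone). LSS was at -0.96 and FDPS at -0.64 against SC5D at 0.23 and SREBF2 at 0.19. SC5D did not pass without SNK-10 DMSO replicate 2 (adjusted p = 0.0736). These 8 lists passed the threshold with the preset correlation (adjusted p between 5.04e-26 and 0.0124) and with an estimated correlation (between 0.00161 and 0.0404).

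A further 6 lists in SNK-10 lost the call with an estimated correlation. Of 40 genes of G2/M and mitosis, 2 rose, 27 fell and 11 did not pass (2 and 28 adjusted over the list alone). KIF20A was at -1.43, PTTG1 at -0.89, CDC20 at -1.11 and BIRC5 at -0.50 against FOXM1 at 0.30 and CDK1 at 0.20 (adjusted p = 0.422 with an estimated correlation). Of 29 p53 targets, 22 rose, 2 fell and 5 did not pass (22 and 2 adjusted over the list alone). MDM2 was at 1.39, FAS at 0.96 and BBC3 at 1.93 (adjusted p = 0.247 with an estimated correlation). Of 24 genes of the unfolded protein response, 7 rose, 14 fell and 3 did not pass (7 and 14 adjusted over the list alone) (adjusted p = 0.390 with an estimated correlation). Of 31 hypoxia and glycolysis genes, 15 rose, 4 fell and 12 did not pass (17 and 4 adjusted over the list alone) (adjusted p = 0.448 with an estimated correlation). Of 24 genes of JAK-STAT and cytokine signalling, 13 rose, 6 fell and 5 did not pass (13 and 6 adjusted over the list alone) (adjusted p = 0.282 with an estimated correlation). Of 14 immune checkpoint and surface target genes, 9 rose, 1 fell and 4 did not pass (9 and 1 adjusted over the list alone) (adjusted p = 0.156 with an estimated correlation). The DNA damage signalling list did not pass (adjusted p = 0.975). Of its 27 genes, 10 rose, 6 fell and 11 did not pass (10 and 7 adjusted over the list alone). ATR was at -0.41, RNF168 at 0.50 and H2AX, chosen after its values were seen, at -0.67. Its median was -0.06 while the test pointed upwards. MAT2A, PPAN, GAB2, ARRDC3, TP53INP1 and DEPP1 overlap other tested genes in the annotation, which leaves the split of their reads uncertain.

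In SNT-16 cells, KLHDC7B rose from 4.39 ± 1.27 to 33.3 ± 1.79 CPM (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.164, adjusted p = 3.89e-15). TP53I3, a p53 target, rose with 2.41 (SE 0.174, adjusted p = 8.73e-13), and PPP1R15A, which encodes a subunit of the phosphatase that reverses the integrated stress response, rose with 2.25 (SE 0.152, adjusted p = 4.02e-08). CXCR3 fell with -2.48 (SE 0.121, adjusted p = 2.05e-11), and the mitotic genes CCNB1 and CDC20 fell with -2.16 (SE 0.126, adjusted p = 2.44e-09) and -1.76 (SE 0.0770, adjusted p = 3.52e-16). The other large rises were in BNIP3L (2.48), ABHD4 (2.48), TNFSF4 (2.35), CCNG2 (2.30) and RGS1 (2.24). The other large falls were in TSPOAP1 (-3.06), CCL2 (-2.02), HPDL (-1.99), TANC2 (-1.92) and SLC39A10 (-1.85). The naming rule took only genes with all 3 icaritin libraries on the same side of all 3 DMSO libraries. TP53I3 overlaps another tested gene in the annotation, which itself rose (0.84 in SNT-16, adjusted p = 0.0276), so the split of their reads is uncertain. In all, 6051 genes (42%) passed the threshold, 3053 higher and 2998 lower, and 519 changed at least 2-fold, 294 of them upwards.

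Of 37 ATF4 and integrated stress response genes in SNT-16, 33 rose, 0 fell and 4 did not pass (33 and 1 adjusted over the list alone). SESN2 was at 1.81, DDIT3 at 1.98 and TRIB3 at 1.67. Of 39 MYC and ribosome biogenesis genes, 0 rose, 37 fell and 2 did not pass (0 and 38 adjusted over the list alone). NOP16 was at -1.38, WDR3 at -1.20 and PPRC1 at -0.92. Of 19 heat shock genes, 0 rose, 13 fell and 6 did not pass (0 and 14 adjusted over the list alone). HSPA8 was at -1.11, STIP1 at -0.92 and FKBP4 at -0.77. Of 24 genes of cholesterol synthesis and SREBP2, 1 rose, 19 fell and 4 did not pass (2 and 19 adjusted over the list alone). DHCR7 was at -0.76 and FDPS at -0.50 against STARD4 at 0.49. Of 35 genes of homologous recombination and the Fanconi anaemia pathway, 24 rose, 1 fell and 10 did not pass (25 and 1 adjusted over the list alone). RAD54L was at 0.63 and EXO1 at 0.59 against FANCF at -0.26. FANCF did not pass without SNT-16 DMSO replicate 2 (adjusted p = 0.0596) or 3 (0.270), SNT-16 icaritin replicate 1 (0.0535) or 3 (0.0889), nor in DESeq2 (0.0717) or on log2(FPKM + 1) (0.111). Of 30 lysosome and autophagy genes, 21 rose, 0 fell and 9 did not pass (22 and 0 adjusted over the list alone). WIPI1 was at 1.27 and MAP1LC3B at 1.08. Of 13 BCL2 family genes, 8 rose, 1 fell and 4 did not pass (8 and 1 adjusted over the list alone). BCL2 was at 0.84, BBC3 at 1.07, BCL2L11 at 0.98 and PMAIP1 at 0.96 against BCL2A1 at -0.82. BCL2A1 did not pass without SNT-16 DMSO replicate 1 (adjusted p = 0.0958) or 3 (0.161), SNT-16 icaritin replicate 2 (0.0799) or 3 (0.106), nor in DESeq2 (0.0985). These 7 lists passed the threshold with the preset correlation (adjusted p between 1.26e-29 and 0.000440) and with an estimated correlation (between 0.000625 and 0.0170).

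A further 7 lists in SNT-16 lost the call with an estimated correlation. Of 40 genes of G2/M and mitosis, 1 rose, 34 fell and 5 did not pass (1 and 34 adjusted over the list alone). KIF20A was at -1.73, PTTG1 at -0.78 and BUB1 at -0.58 against CDK1 at 0.16 (adjusted p = 0.132 with an estimated correlation). CDK1 did not pass without SNT-16 DMSO replicate 3 (adjusted p = 0.129) or SNT-16 icaritin replicate 3 (0.169). Of 29 p53 targets, 25 rose, 0 fell and 4 did not pass (25 and 0 adjusted over the list alone). MDM2 was at 0.99, FAS at 0.87 and BTG2 at 0.96 (adjusted p = 0.0615 with an estimated correlation). Of 40 interferon-stimulated genes, 5 rose, 25 fell and 10 did not pass (5 and 25 adjusted over the list alone) (adjusted p = 0.0615 with an estimated correlation). Of 45 genes of G1/S and DNA replication, 27 rose, 4 fell and 14 did not pass (27 and 4 adjusted over the list alone) (adjusted p = 0.140 with an estimated correlation). Of 31 hypoxia and glycolysis genes, 19 rose, 1 fell and 11 did not pass (21 and 1 adjusted over the list alone) (adjusted p = 0.183 with an estimated correlation). Of 12 FOXO targets, 5 rose, 1 fell and 6 did not pass (5 and 2 adjusted over the list alone) (adjusted p = 0.132 with an estimated correlation). Of 41 cytosolic ribosomal protein genes, 19 rose, 2 fell and 20 did not pass (21 and 2 adjusted over the list alone) (adjusted p = 0.562 with an estimated correlation). The DNA damage signalling list did not pass (adjusted p = 0.806). Of its 27 genes, 9 rose, 8 fell and 10 did not pass (9 and 8 adjusted over the list alone). ATR was at -0.48, TIMELESS at 0.37, RNF168 at 0.36 and H2AX, chosen after its values were seen, at -1.01.

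Over the 3 lines together, 3942 genes changed in the same direction in every line, 1877 upwards and 2065 downwards, where independent lists of these sizes would share 179 and 180. The largest average rises among them were in CCNG2, with a log2 fold change of 2.79 (SE 0.0650, adjusted p = 6.29e-27), and KLHDC7B, with 2.52 (SE 0.122, adjusted p = 1.50e-17). RGS1, TSC22D3 (a glucocorticoid-induced gene), BNIP3L, KLHL24, TNFSF4, ABHD4, ARRDC3 and PPP1R15A followed, between 2.15 and 2.46. The largest average falls were in TSPOAP1, with -3.03 (SE 0.102, adjusted p = 4.38e-19), HPDL, with -2.28 (SE 0.0820, adjusted p = 1.29e-23), and CXCR3, with -2.28 (SE 0.0710, adjusted p = 7.74e-15). SLC39A10, TANC2, CCNB1, CCL2, the cytokine gene OSM, the mitotic kinesin gene KIF20A and the protease gene MMP12 followed, between -2.03 and -1.60. At least 2-fold changes in every line were seen for 105 genes upwards and 85 downwards, and 220 genes passed the threshold in opposite directions in a pair of lines. On the average over the lines, 8884 genes (61.7%) passed the threshold, 4566 higher and 4318 lower, and 558 changed at least 2-fold. Across 9332 genes with at least 10 CPM, Pearson's r of the log2 fold changes was 0.89 between SNT-8 and SNT-16, 0.82 between SNT-8 and SNK-10 and 0.79 between SNK-10 and SNT-16 (Spearman's rho 0.89, 0.81 and 0.78). Over all 14396 tested genes Pearson's r was lower, at 0.56, 0.55 and 0.48; genes are not independent replicates. The 3 contrasts shared no libraries, and the close resemblance of the SNT-8 and SNT-16 controls applies to each of these counts.

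On average, the 7 lists that passed with an estimated correlation in all 3 lines passed as well. The average is drawn from the same libraries, so this is no separate test of them. The ATF4 list had a median log2 fold change of 0.82 (34 of 37 rose and 0 fell; adjusted p = 1.08e-20, and 0.00290 with an estimated correlation), and the MYC and ribosome biogenesis list had -0.88 (all 39 fell; 1.16e-23 and 0.00344). The medians were -0.66 for heat shock genes (0 of 19 rose and 17 fell; 8.03e-10 and 0.0132) and -0.46 for cholesterol synthesis (4 of 24 rose and 19 fell; 3.78e-07 and 0.0132). They were 0.20 for homologous recombination and Fanconi anaemia (25 of 35 rose and 6 fell; 6.12e-05 and 0.00344), 0.32 for lysosome and autophagy (22 of 30 rose and 1 fell; 3.01e-07 and 0.00375) and 0.31 for the BCL2 family (10 of 13 rose and 1 fell; 0.00136 and 0.0132). A further 7 lists passed only with the preset correlation. They were G2/M and mitosis (2 of 40 rose and 37 fell; median -0.44; adjusted p = 0.227 with an estimated correlation), p53 targets (27 of 29 rose and 0 fell; median 0.79; adjusted p = 0.114 with an estimated correlation) and FOXO targets (8 of 12 rose and 1 fell; adjusted p = 0.0820 with an estimated correlation). The others were hypoxia and glycolysis (23 of 31 rose and 2 fell, with VEGFA at 1.15 and NDRG1 at 1.10; adjusted p = 0.336 with an estimated correlation) and interferon-stimulated genes (5 of 40 rose and 23 fell, with BST2 at -0.56 and OAS2 at -0.69; adjusted p = 0.336 with an estimated correlation). The last were G1/S and DNA replication (25 of 45 rose and 15 fell, with CDT1 at 0.95 and LIG1 at 0.58; adjusted p = 0.572 with an estimated correlation) and cytosolic ribosomal proteins (27 of 41 rose and 1 fell, with RPS19 at 0.20 and RPSA at 0.16; adjusted p = 0.592 with an estimated correlation). In SNK-10 alone, interferon-stimulated genes did not pass with the preset correlation (13 of 40 rose and 7 fell, median -0.01, adjusted p = 0.924). Nor did G1/S and DNA replication (18 of 45 rose and 17 fell, 0.618) or cytosolic ribosomal proteins there (4 of 41 rose and 3 fell, 0.453). For these lists the average does not stand for a change in each line. Counts adjusted over the list alone equalled those over all genes on average except for FOXO targets, where 9 in place of 8 rose. Of 100 splits of the libraries into arms within their lines, 7 gave at least the 14 lists that passed with the preset correlation, the real split included.

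The DNA damage signalling list did not pass on average: 11 of 27 rose and 9 fell, with ATR at -0.49, ATRIP at -0.65, TIMELESS at 0.37 and TIPIN at -0.62 (adjusted p = 0.947). Nor did the lists for the drugs of the GELOX regime. For gemcitabine handling, 6 of 12 rose and 4 fell, with the activating kinase gene DCK at 0.44 and the nucleoside transporter gene SLC29A1 at -0.51 (adjusted p = 0.404). For platinum handling, 5 of 16 rose and 6 fell, with the damage sensor gene XPC at 0.59, the metallothionein gene MT2A at 0.38 and the repair gene ERCC1 at -0.32 (0.937). On log2(FPKM + 1), ERCC1 was at -0.064 and did not pass (adjusted p = 0.0807). For asparagine and glutamine metabolism, 4 of 9 rose and 3 fell, with GOT1 at 0.53 (0.685). The asparagine synthetase gene ASNS is also in this list. Its response differed between lines, with a rise in SNK-10, and is given with those differences below. Of the metabolic and stress lists, the unfolded protein response did not pass (8 of 24 rose and 13 fell, with HSP90B1 at -0.80, CALR at -0.69 and SDF2L1 at -1.44; adjusted p = 0.0605, which became 0.0483 without SNT-8 icaritin replicate 1, 0.0416 without SNK-10 icaritin replicate 3 and 0.0481 without SNT-16 icaritin replicate 3). Nor did NRF2 targets (9 of 23 rose and 7 fell, with SLC7A11 at 1.14 and GCLM at 0.71; adjusted p = 0.421) or fatty acid synthesis (4 of 13 rose and 5 fell, with FASN at -1.25 and SCD at -0.70; 0.229). The nuclear genes of oxidative phosphorylation did not pass either (7 of 35 rose and 17 fell, with ATP5MC3 at -0.49 and SDHA at 0.35; 0.125). Signalling lists that did not pass were NF-kB targets (9 of 30 rose and 12 fell, with LTB at -1.52 and TNFAIP3 at 0.88; adjusted p = 0.404) and JAK-STAT and cytokine signalling (12 of 24 rose and 11 fell, with PRDM1 at 0.57 and JAK1 at 0.52; 0.712). Immediate early genes (4 of 13 rose and 5 fell, with JUN at -1.08 and KLF6 at 0.39; 0.954) and ERK feedback genes (1 of 11 rose and 3 fell, with DUSP5 at 1.58 and DUSP6 at -0.83; 0.604) did not pass either. Cell marker lists that did not pass were NK and cytotoxic cells (5 of 27 rose and 11 fell, with IFNG at -1.12 and TBX21 at -1.18; adjusted p = 0.176) and T cells (2 of 14 rose and 7 fell, with CD3D at -0.50 and CD247 at 0.24; 0.212). Markers of myeloid cells (2 of 6 rose and 1 fell; 0.447) and of fibroblasts and epithelia (3 of 7 rose and 0 fell; 0.358) did not pass either. The same held for MHC class II (0 of 10 rose and 5 fell, with HLA-DMA at -0.55 and HLA-DMB at -0.61; 0.105) and immune checkpoints (6 of 14 rose and 3 fell, with CTLA4 at 2.08 and TNFRSF8 at -0.73; 0.332). The median and the mean differed in sign for DNA damage signalling (0.04 and -0.04), JAK-STAT signalling (0.10 and -0.03), platinum handling (-0.04 and 0.04) and immediate early genes (0.03 and -0.12). Of lists too short to test, the LXR targets LPCAT3 and MYLIP changed by -0.25 (adjusted p = 1.09e-05) and 0.50 (5.04e-05). The AHR target CYP1A2 changed by 0.40 (0.00330), and the B cell genes PAX5 and EBF1 by -0.54 (2.56e-05) and 0.40 (0.00621). In SNK-10 alone, CYP1A2 did not pass in DESeq2 (adjusted p = 0.102), without a count filter (0.0837) or with library totals (0.0561). It also lost this call with only the libraries of the line (0.0627). The same held without any 1 of most of the SNK-10 libraries (adjusted p between 0.0566 and 0.143). These lists had 4 (LXR), 4 (AHR) and 3 (B cell) tested members. The remaining members are not given, so no direction of a list can be read from these genes.

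**Figure D3:**
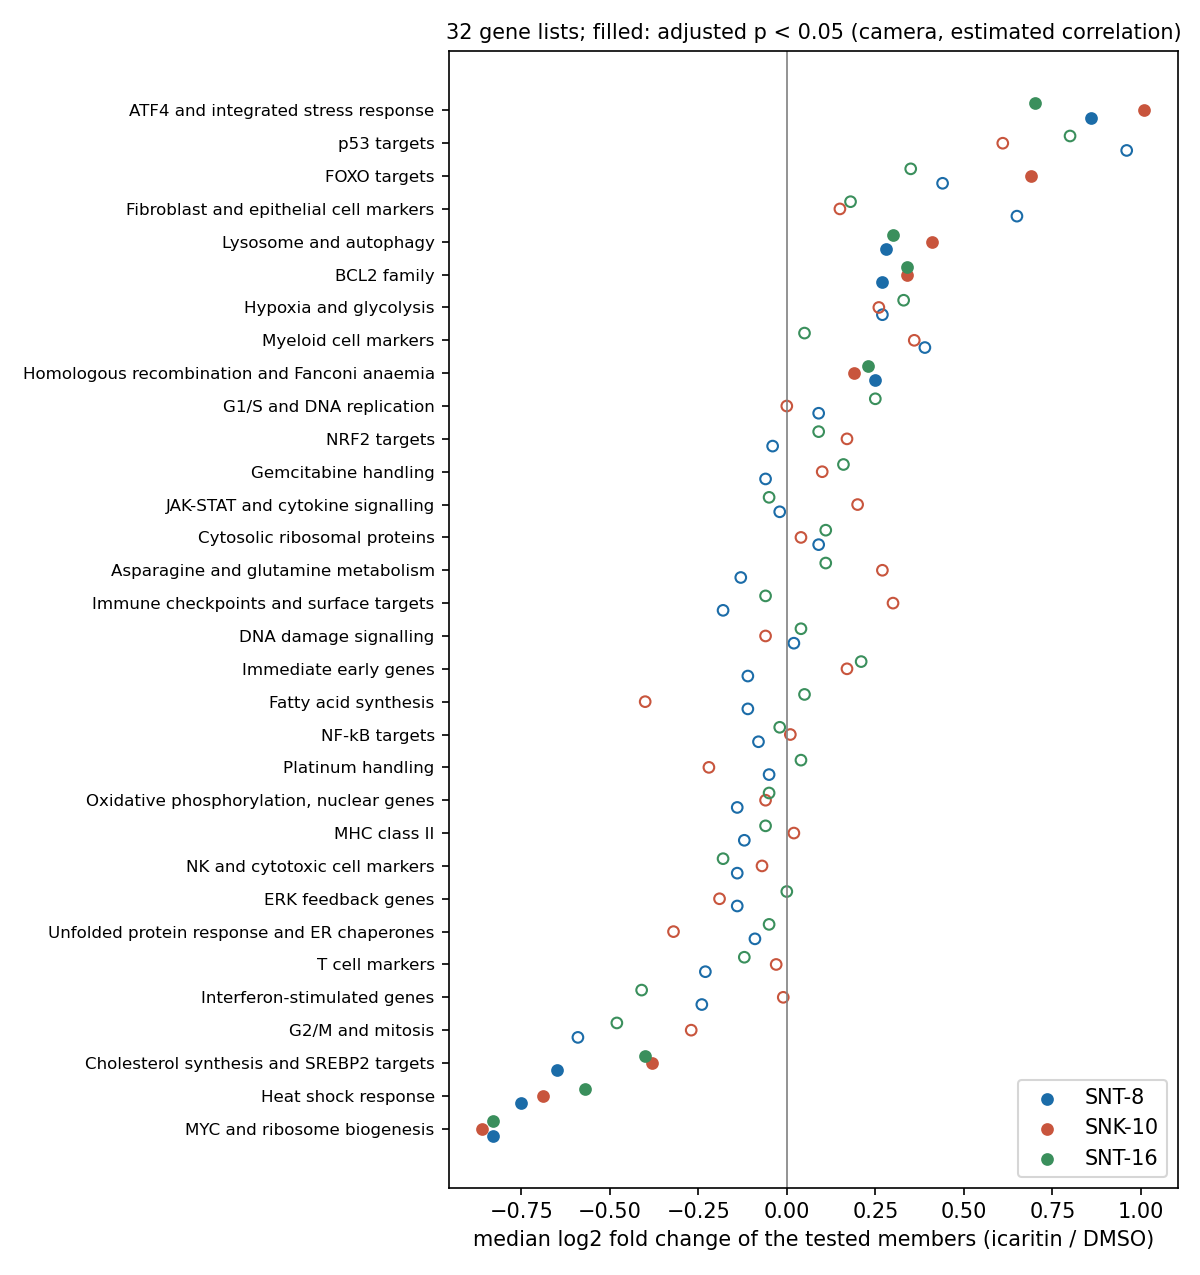
Median log2 fold change of icaritin against DMSO for each tested gene list in the 3 lines, in the order of the medians on average, with filled points for lists that passed the threshold with an estimated correlation. Furthest up lie p53 targets in SNT-8 (0.96) and SNT-16 (0.80) and the ATF4 list in SNK-10 (1.01), and the MYC and ribosome biogenesis list lies furthest down in each line.

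To ask whether the lines responded alike, the response was compared between them, and the clearest differences set SNK-10 apart from both SNT lines. FADS2, a fatty acid desaturase gene, rose in SNT-8 (1.31) and SNT-16 (0.64) and fell in SNK-10 (-0.52; interaction adjusted p = 3.66e-12). XAF1, an interferon-stimulated gene, changed by -0.25 in SNT-8, -0.67 in SNT-16 and 0.35 in SNK-10 (3.93e-12). ARID5A changed by -0.36, -0.44 and 0.32 (1.08e-10). PIM1, a kinase gene induced by cytokines, rose in SNK-10 (0.62), fell in SNT-16 (-0.29) and was at -0.08 in SNT-8, which did not pass the threshold (interaction 5.18e-12). Without SNT-8 icaritin replicate 3, PIM1 was at -0.13 in SNT-8 and passed (adjusted p = 0.0375). LTA, a lymphotoxin gene, changed by -1.40 in SNT-8, -1.12 in SNT-16 and -0.42 in SNK-10 (5.02e-11), and DHRS2 by -1.22, -0.88 and -0.33 (1.08e-10). The response of 2053 genes (14.3%) differed between lines, of which 673 were among the 3942 that changed in the same direction in every line. Between SNT-8 and SNT-16 the response of 63 genes differed, between SNT-8 and SNK-10 of 1551 and between SNK-10 and SNT-16 of 1801.

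With an estimated correlation, 5 lists differed in their response between lines. NF-kB targets were higher in SNK-10, by a median log2 difference of 0.26 over SNT-16 (adjusted p = 0.00421 with an estimated correlation) and with SNT-8 minus SNK-10 at -0.21 (0.00133). The JAK-STAT list was also higher in SNK-10, by 0.25 over SNT-16 (0.0212) and with SNT-8 minus SNK-10 at -0.21 (0.0169). Interferon-stimulated genes were higher in SNK-10 than in SNT-16 by 0.4 (0.0272). Cholesterol synthesis fell further in SNT-8, with a difference of -0.29 from SNK-10 (0.0169) and -0.26 from SNT-16 (0.00706), and homologous recombination and Fanconi anaemia rose less in SNK-10 than in SNT-16, by -0.06 (0.0303). More lists passed with the preset correlation alone. Among them, G2/M and mitosis had SNT-8 minus SNK-10 at -0.26 (adjusted p = 1.33e-09, and 0.251 with an estimated correlation). For p53 targets this difference was 0.33 (9.06e-09 and 0.209). The asparagine synthetase gene ASNS, a member of the stress response list and of the asparagine and glutamine list, was chosen after its values were seen. It was at -0.13 in SNT-8, 1.23 in SNK-10 and -0.16 in SNT-16 (interaction adjusted p = 4.18e-05). Its average over the lines did not pass in DESeq2 (0.313, adjusted p = 0.0595), without a count filter (0.0752) or on log2(FPKM + 0.1) (0.0658). Leaving out any 1 of many libraries, some from each line, also lost the call (adjusted p between 0.0546 and 0.320). This average was lowest, at 0.19, without SNT-16 icaritin replicate 1 (adjusted p = 0.320). FADS2 overlaps FADS1, and the split of their reads is uncertain.

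**Figure D4:**
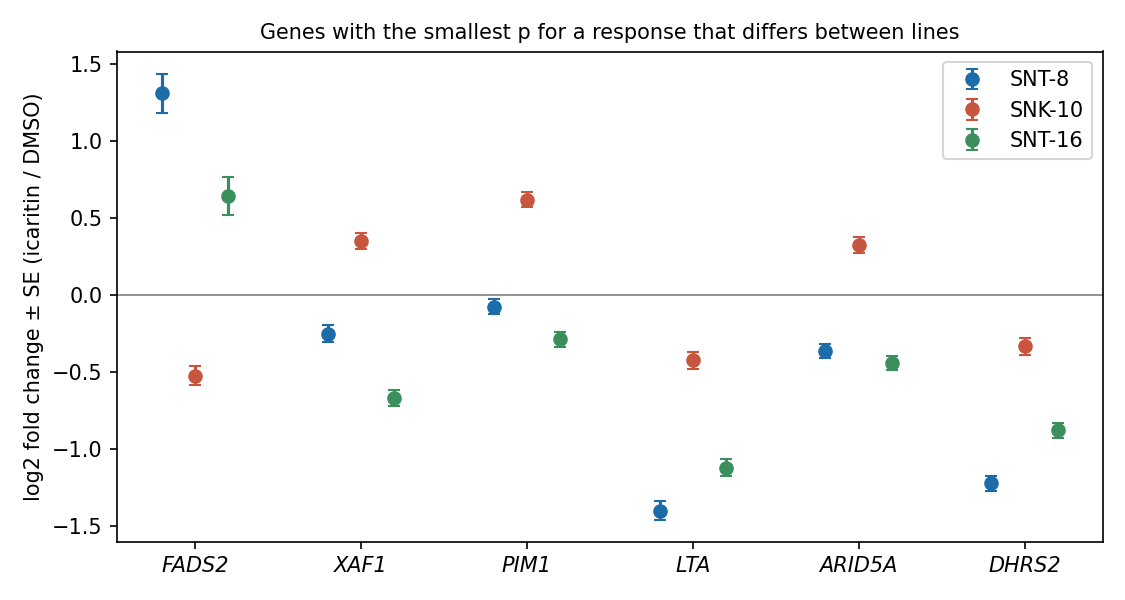
Log2 fold change of icaritin against DMSO in each line for 6 of the 8 genes with the smallest interaction p, with points for the fit and bars for its SE. For XAF1 and ARID5A, SNT-8 and SNT-16 lie below 0 and SNK-10 above it.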

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

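The tests of single exchanged libraries, of more mitochondria, of a stronger response in a single library and of its depth were chosen only after the results they measure were seen, and the split test with an estimated correlation was added after other splits were seen to give as many lists with the preset correlation.

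The response to icaritin differed between lines, by the interaction test, for 2053 genes, and genes named for their changes were among them. The log2 response of SNT-8 minus that of SNK-10 was 1.58 for KLHDC7B, 0.85 for RGS1, 1.99 for TP53I3, 1.83 for FADS2, -1.39 for CXCR3, -1.03 for TANC2, -1 for CCL2, -2.26 for GAB2, -0.65 for CDC20, -0.46 for KIF20A, -0.97 for LTA and -0.89 for DHRS2. The response of SNK-10 minus that of SNT-16 was 1.1 for CCNG2, 0.91 for KLHL24, 1.27 for CTH, 0.77 for ARRDC3, 1.02 for XAF1, 0.9 for PIM1, 0.76 for ARID5A, -0.68 for DANCR, -0.45 for RRS1 and -0.61 for MAT2A. The response of SNT-8 minus that of SNT-16 was -0.64 for MMP12 and 1.17 for TSC22D3. That pair did not pass on its own for TSC22D3 (adjusted p = 0.124), while SNT-8 minus SNK-10 did, at 0.96 (adjusted p = 0.0176). Each gene is given for its pair of lines with the largest difference; GAB2 was too weakly expressed in SNT-8 for its fold there to be read. Of the gene lists, with an estimated correlation, the median response of SNT-8 minus SNK-10 was -0.29 for cholesterol synthesis, -0.21 for NF-kB targets and -0.21 for JAK-STAT signalling, and that of SNT-8 minus SNT-16 was -0.26 for cholesterol synthesis. The median response of SNK-10 minus SNT-16 was 0.4 for interferon-stimulated genes, 0.26 for NF-kB targets, 0.25 for JAK-STAT signalling and -0.06 for homologous recombination and Fanconi anaemia.

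The libraries of SNT-8 and SNT-16 resembled each other. Of the 12 libraries, 0 lay nearer to the same arm of the other line than to its own group, which argues against single libraries exchanged between the lines. An exchange of a whole group or line would also give 0 and cannot be seen by this test. Genes on in the DMSO libraries of either SNT line and without a count in the other came to 0% of the mean of the pairs with SNK-10 (53 and 12 genes, mean 32.5). All of those 53 and 12 genes were on in SNK-10, and genes on in an SNT line and without a count in SNK-10 also numbered 0, so this count does not decide whether the lines are 2 names for one cell population. Between their controls 148 genes differed at least 2-fold, the labels do not say how the lines were derived, and this stays open.

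Mitochondrial ribosomal RNA took a larger share after icaritin: on average over the lines, RNR2 rose by 1.17 and RNR1 by 1.09 on the log2 scale. More mitochondria per cell could raise this share. The 35 nuclear genes of oxidative phosphorylation did not rise with it, at a median change of -0.06 (quartiles -0.21 and 0.05). Their RNA does not count mitochondria per cell, so this explanation stays open. Less complete removal of RNA without a poly(A) tail could also raise the share. The 11 other tested RNAs of this kind had a median change of 0.22, which is 18.4% of that of RNR2. All were weakly expressed, with means between 0.684 and 8.79 CPM. RNU6-2 and RNU6-9 held identical values (-0.92 each), so they may not be separate measurements. The 11 RNAs went both ways (quartiles -0.52 and 0.84), and this explanation stays open too. A change in the transcription or decay of mitochondrial RNA under icaritin was not tested.

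Icaritin replicate 2 of SNT-8 stood apart from the other icaritin replicates of its line, with 42.4 CPM of PLK1 against 82.4 and 89.2. Lower depth is argued against, since its total count was 101% of the mean of the others. Across 9332 genes its deviation from the other replicates correlated with the response of SNT-16 (r = 0.33, slope 0.19), which would be consistent with a stronger response to icaritin in this library, such as a higher dose or a longer exposure; the labels record neither per library.

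Other splits of the libraries were fitted for each count. Within a line there are 10 splits, too few for a share under 0.05. In SNT-8, 1 split (the real one) gave 7062 genes and the highest other gave 0; in SNK-10, 1 split gave 6970 and the highest other 1; in SNT-16, 1 split gave 6051 and the highest other 0. For gene lists with the preset correlation, 2 splits in SNT-8 gave at least 15 lists (highest other 15), 1 in SNK-10 gave 14 (highest other 11) and 5 in SNT-16 gave at least 14 (highest other 15). Over the 3 lines, 1 of 100 splits, the real one, gave the 8884 genes of the average (highest other 6427). Likewise 1 of 100 gave the 3942 genes shared by all lines (highest other 84). A random split of these libraries is therefore unlikely to give either count. If the replicates of an arm were not separate cultures, these splits cannot tell icaritin from a difference between cultures. For the interaction, 3 of 100 splits gave at least 2053 genes; the highest other gave 8351, several times the real count, which points to a structure of the samples, since a split that turns the arms of a line around turns its response into a difference between lines. These splits stand for no response at all and not for an equal response in each line, so they do not decide whether chance could give the differences between lines. For gene lists on average, 7 of 100 splits gave at least 14 with the preset correlation (highest other 18), so chance is not excluded for that number; with an estimated correlation 2 of 100 gave at least 7, and the highest other gave 9, more than the real split. That share is under 0.05, but this version was added after the share of the other was not, so chance is not taken as excluded.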

How the results depend on the processing

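Each alternative was chosen before the data were examined, except the counts without the SNT-8 or without the SNT-16 libraries, which were added after seeing the data. RLE size factors, library totals, the count filters, DESeq2, the FPKM tests, a replicate block and only the libraries of the line kept each count of changed genes within 1.5 times its value and each fall of PLK1 past the threshold, between -1.812 and -1.22 over the 3 lines. The share of higher genes moved by less than 10 percentage points and the median of all genes by less than 0.1 with another scaling. In SNT-8 the share was 49% with TMM and 56% with library totals. All these scalings set levels relative to the library, so a change in total RNA per cell could not be seen with any of them.

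With a log2 fold change of at least 1, the counts were 743 in SNT-8, 709 in SNK-10, 519 in SNT-16, 558 on average and 190 in the same direction in all 3 lines, because most changes were smaller than that. With adjusted p under 0.01, 1095 genes differed in response between lines, as the stricter threshold requires fewer. Camera with an estimated correlation called 7 lists in SNT-8, 8 in SNK-10, 7 in SNT-16 and 7 on average. Fry, which does not compare a list with other genes, called 24, 23, 26 and 29. For the immediate early genes on average, fry pointed up (adjusted p = 0.0154) where camera pointed down, and the cause was not tested. Their median did not turn, at 0.022 on log2 CPM and 0.03 in the gene fit. DHRS3, named for its rise in SNK-10, was at -0.10 on average and at 0.621, 0.557 and 0.621 in the FPKM tests with 1 added, with 0.1 added and without a filter; it had no count in SNT-8 and almost none in SNT-16, so its average (SE 165) is no usable estimate, and the cause was not tested.

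Leaving out each library in turn gave 6373 to 7244 changed genes in SNT-8, 6305 to 7242 in SNK-10, 5374 to 6368 in SNT-16, 8600 to 8858 on average, 3690 to 3951 in all lines and 1649 to 2503 for the interaction. The lists called ranged from 15 to 17 in SNT-8, 14 to 14 in SNK-10, 14 to 16 in SNT-16 and 14 to 15 on average. PLK1 ranged from -1.649 to -1.496 on average, -1.972 to -1.514 in SNT-8, -1.278 to -1.186 in SNK-10 and -1.808 to -1.66 in SNT-16. In these fits an arm of 2 libraries is assumed to vary like the other groups. Calls of lists that a single library or another setting of the fit changed, besides those given with their lists, were near the threshold. In SNT-8, oxidative phosphorylation genes (adjusted p = 0.0507) passed with any 1 of 11 libraries left out (0.0248 to 0.0491), with RLE size factors (0.0472) and with the replicate block (0.0495), and fatty acid synthesis (0.0659) without DMSO replicate 3 or icaritin replicate 1 (both 0.0458). The unfolded protein response in SNT-8 (0.07) passed without icaritin replicate 1 (0.0457). In SNT-16, T cell markers (0.074) passed without icaritin replicate 2 (0.0377), and MHC class II genes (0.0772) without icaritin replicate 2 (0.0202) or 3 (0.0307). For 604 results of named genes in a line or on average, the fits without a library gave the same outcome, past the threshold or not, 10804 times, lost a call 58 times and gained it 10 times; the other settings lost it 53 times, gained it 8 times and turned 3 directions (all DHRS3). Among them, BRINP2 in SNK-10 lost its call without DMSO replicate 2 or icaritin replicate 1 (adjusted p = 0.0523 and 0.0659) and DEPP1 in SNT-16 gained one without icaritin replicate 2 (0.0437).

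The replicate numbers did not pair the arms: the correlation across genes of DMSO and icaritin libraries with the same number, after removing group means, lay between -0.13 and 0.04. With the replicate block, 6847, 6788 and 5819 genes changed in SNT-8, SNK-10 and SNT-16, 8749 on average, 3813 in all lines and 1729 differed between lines. With it, oxidative phosphorylation genes in SNT-8 passed, BCL2A1 in SNT-16 and CYP1A2 in SNK-10 did not (adjusted p = 0.0581 and 0.0575), and no other call of a named gene or list changed. Without the SNT-8 libraries, 7983 genes changed on average and 4553 in the same direction in both remaining lines; without the SNT-16 libraries, these were 8133 and 4566.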

Other observations

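The test of cells held in mitosis was chosen only after its result was seen; the test of SNT material in SNK-10 was devised after the one-sided pattern was seen, before its own outcome was.

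The genes on in SNT-8 were never absent from SNK-10, while some genes on in SNK-10 were nearly absent from SNT-8. Sex-linked marker genes were left out of these counts. Of 7549 genes with at least 20 CPM in SNT-8, 8 were below 1 part in 8 of that level in SNK-10 and none below 4.7%. The other way round, 185 of 7699 were below 1 part in 8. RNA or cells of an SNT line in the SNK-10 libraries could give such a floor. To test it, the responses of genes low in SNK-10 were compared with their responses in SNT-8. For 27 genes, at 4.7% to 16.5% of their SNT-8 level (median 14.6%), the median absolute difference of the log2 responses was 0.15, against 0.26 for genes matched on their SNK-10 level, or 57.9%; 1.7% of 10000 matched sets were as low. Such material can give no more than 4.7% of the SNT-8 level, which is 32.2% of the level of these genes in SNK-10 at the median, so most of their RNA would be that of SNK-10 itself. The test therefore does not decide, and the explanation stays open.

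A block of cells in mitosis, known from inhibitors of PLK1, would raise the RNA of G2/M and mitosis genes. Of the 40 tested, 5% (2 genes, FOXM1 and CDK1) were higher on average and 37 fell. As a list they did not pass with an estimated correlation (adjusted p = 0.227), and this test restates the fall from which it was drawn. The falls of the single genes show no gain of such RNA at 12 h for most of them. Cells in mitosis were not counted, so whether icaritin held cells there stays open.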
